A study of Mus musculus with 11 samples.

How the data were processed

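RNA was sequenced from mesenchymal cells of C57BL6 mouse lung, sorted as negative for EpCAM, CD45 and CD31, at day 7 or 14 after PNX or sham surgery. Per the labels, RNA was extracted with a column kit for small samples and libraries were made with a kit for single cells or low input. The read counts per gene were made by the authors from mm10, with bcl2fastq 2.20.0.422 named in the submitters' processing notes; the aligner, the counting tool, the annotation, the strand setting and any filter are not stated. The values, 1 column for each of 11 libraries, were checked to be whole numbers that were neither scaled nor on a log scale, and 1371 symbols had no count in any library. All columns were used.

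Groups were taken from the labels: surgery (sham or PNX) and day (7 or 14). Counts were analysed in R 4.3.3 with edgeR 4.0.16. filterByExpr by group removed 8400 genes and left 16011. TMM factors, estimateDisp and a robust quasi-likelihood fit of 4 group means on all 11 libraries (7 residual degrees of freedom, median prior degrees of freedom 10.8, square root of the dispersion 0.442) gave F tests for PNX against sham at day 7, at day 14 and in the mean of both days, the interaction, and day 14 against day 7 within PNX and within sham. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Adjusted p for genes is from edgeR wherever no other tool is named. The standard error of a log2 fold change was derived from the test, as its absolute value divided by the square root of F. It is approximate for genes with few counts in a group. Its median was 0.44 at day 7, 0.50 at day 14 and 0.33 in the mean of both days. CPM values are scaled by TMM factors, except those of olfactory and vomeronasal receptor genes, which are shares of the total counts. Intervals of count ratios are exact Poisson intervals at 95% and cover counting error only.

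Gene lists numbered 31: alveolar, lipofibroblast and adventitial fibroblasts, alveolar myofibroblasts, smooth muscle, pericytes, mesothelium, matrix, fibrosis-associated fibroblasts, proliferation, niche ligands, Wnt, BMP, hedgehog, YAP and SRF targets, retinoid, inflammatory, interferon, hypoxia, cholesterol, unfolded protein, mitochondrial, immediate early and clock genes, and markers of 7 other cell types. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The mitochondrial list had no member in the table and was not tested. The comparisons, the model, the lists, the rule for named genes and a first group of other settings were fixed before the data were examined.

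Named genes are, for PNX against sham at each day, up to 10 genes in each direction with the largest log2 fold change past the threshold, at a mean log2 CPM of at least 1, with groups that do not overlap, predicted or clone-named genes left out. For the other comparisons up to 5 in each direction were taken, and where fewer than 5 passed, those of smallest p filled up to 5. Up to 4 members of each list with the smallest p per day, and 21 genes of the alveolar niche and of gated-out cells, were added. Itga8, Col3a1, Ctss and the list members named in the comparisons between days were chosen after their values were seen, apart from those the rule gave.

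The settings fixed in advance were DESeq2 1.42.0, limma voom with sample weights, RLE size factors, total counts without TMM factors, no filter on low counts, a filter of 1 CPM in 5 samples, only the groups compared, the replicate number as a block, a test against a fold of 1.5, and leaving out each library in turn. Settings chosen after seeing the data were a covariate for X and Y transcripts, only the libraries with counts on 4 Y-linked genes, a covariate for the background on 1455 olfactory and vomeronasal receptor genes, the 3 libraries of highest background left out, and a GC offset alone or with the replicate block. The 3 libraries of highest background were sham day 7 replicate 2, PNX day 7 replicate 2 and sham day 14 replicate 1. Without them 1 sham library of day 14 is left. The GC offset was a lowess trend of span 0.5 on 9665 genes above a log2 CPM of 3. Symbols were matched to GENCODE M21 for locations in mm10 and GC content, 23334 directly and 667 through synonyms (98.3%). Since the strand setting is unknown, reads of overlapping genes cannot be assigned with certainty. The steps were tested on simulated data with planted changes: at day 7 edgeR called 10% of 2-fold, 78% of 4-fold and 94% of 8-fold changes, with 5 false among 150 calls, and DESeq2 had 33 false among 192. At day 14 edgeR called 60% of 4-fold changes. The simulated counts came from a single run and were independent between genes, without background, GC trend or cells carried through the sort. Changes were planted only in the better expressed genes. These shares may therefore not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.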

Results

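Gene expression was measured by RNA sequencing in mesenchymal cells of the mouse lung after pneumonectomy (PNX), the surgical removal of lung tissue, or after sham surgery. The cells came from C57BL6 mice and were sorted by flow cytometry as negative for EpCAM, CD45 and CD31, a gate that excludes epithelial, haematopoietic and endothelial cells. There were 3 libraries for sham at day 7, 3 for PNX at day 7, 2 for sham at day 14 and 3 for PNX at day 14, 11 in all. The table held whole read counts per gene symbol, of which 16011 were tested. Total counts ranged from 4082935 to 8362119 in sham at day 7, from 2963341 to 7614122 in PNX at day 7, from 2539628 to 9008592 in sham at day 14 and from 4733716 to 7895688 in PNX at day 14. No label states that the replicates were separate animals, so the p-values measure the spread between these libraries, which may be technical in part. Levels of single genes are given below as CPM, the counts of a gene as a share of the library's counts, scaled by TMM factors, as mean ± SD over the libraries of a group.

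The libraries differed in background, in markers of other cells and in the GC content of their genes. Olfactory and vomeronasal receptor genes, which lung mesenchyme does not normally express, took from 89.9 to 1606 CPM, here as a share of total counts without TMM factors. This background fell with total counts over the 11 libraries (Pearson r = -0.88, permutation p = 3e-05; Spearman rho = -0.92, permutation p = 0.00022; 2-sided). It still did so without the 2 libraries farthest from the median depth (r = -0.86). Benjamini-Hochberg adjustment over the 2 relations computed gave 6e-05 for r and 0.00044 for rho. The background is itself divided by total counts, so a fixed number of such counts in each library would also give a fall. The counts before division were not tested. Genes with a count also fell in number with total counts (r = -0.76, permutation p = 0.00943, adjusted 0.00943; rho = -0.85, permutation p = 0.00174, adjusted 0.00174; r = -0.65 without the 2 farthest). No batch is named in the labels, so neither relation could be recomputed within batches. Haematopoietic markers, a list of 25 genes, averaged 4.88 and 4.84 log2 CPM in the 2 sham libraries of day 14 and at most 3.58 in the other libraries. The rank correlation of GC content with a gene's log2 CPM in a library, less its mean over libraries, was -0.12 to 0.50 in sham at day 7 and -0.17 to 0.31 in PNX at day 7. It was 0.08 and -0.39 in sham at day 14 and -0.38 to -0.32 in PNX at day 14. Haemoglobin transcripts took 0.0344 to 9.06% of counts, and Sftpc, the surfactant gene of type II alveolar cells, took 0.00194 to 1.34%. In 4 libraries no Y-linked count was present: sham day 7 replicate 3, sham day 14 replicate 1, and PNX day 14 replicates 2 and 3. All 3 PNX libraries of day 7 held Y-linked counts. Scaling by total counts in place of TMM factors moved the median log2 fold change of all genes between PNX and sham by 0.18 at day 7 and -0.19 at day 14, that of the interaction by -0.37 and that between days after PNX by -0.29; fold changes below are relative to the TMM scale.

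**Figure D1:**
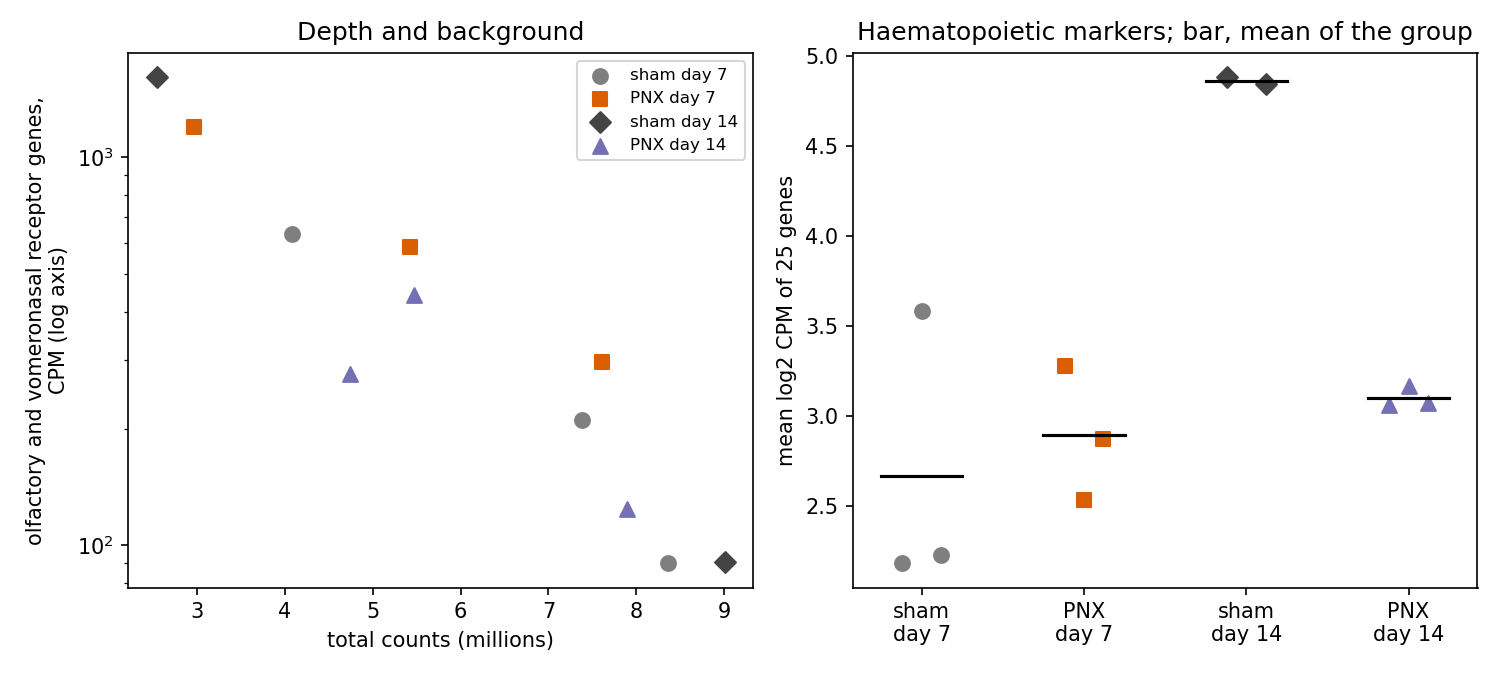
Left, olfactory and vomeronasal receptor genes in CPM without TMM factors (log axis) against total counts, 1 point per library. Right, mean log2 CPM of 25 haematopoietic markers in each library, with a bar for the mean of each group; the 2 sham libraries of day 14 stand at 4.88 and 4.84, above all others.

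At day 7 after surgery, cells from PNX lungs were compared with cells from sham lungs, to find which genes differ early after lung tissue is removed. 6 genes rose, and each was higher in all 3 PNX libraries than in any of the 3 sham libraries. Spp1, which encodes the secreted matrix protein osteopontin, rose from 12.2 ± 5.40 to 409 ± 411 CPM (log2 fold change 5.06 ± 0.70 SE, adjusted p = 0.0216 by edgeR with Benjamini-Hochberg adjustment). The 3 PNX libraries stood at 216, 881 and 130 CPM, and without replicate 2 of PNX day 7 the log2 fold change of Spp1 was 3.79 ± 0.47 (adjusted p = 0.00168). Cthrc1, which encodes a secreted protein of matrix-producing fibroblasts, rose from 8.59 ± 3.01 to 150 ± 43.6 CPM (4.11 ± 0.42, adjusted p = 0.000211). Adam12, a metalloprotease gene, rose from 2.31 ± 0.25 to 26.4 ± 9.46 CPM (3.51 ± 0.55, adjusted p = 0.0216). Timp1, an inhibitor of matrix metalloproteinases, rose from 75.7 ± 10.9 to 405 ± 22.2 CPM (2.42 ± 0.32, adjusted p = 0.00505). The other 2 were Mki67, a marker of cycling cells, from 7.75 ± 3.64 to 48.5 ± 15.3 CPM (2.64 ± 0.44), and Ckap2, which encodes a spindle protein, from 2.15 ± 0.32 to 16.2 ± 4.13 CPM (2.89 ± 0.48), each at adjusted p = 0.0337. In mm10 coordinates Spp1 lies on chromosome 5 (104435118 to 104441050), Cthrc1 on chromosome 15 (39076932 to 39087121), Adam12 on chromosome 7 (133883199 to 134232146) and Timp1 on chromosome X (20870166 to 20874735). Spp1 overlaps the predicted gene Gm42793 on the same strand, so reads of the pair may have been shared.

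No gene passed the threshold as lower after PNX at day 7 with edgeR, although 1292 were lower at an unadjusted p under 0.05, beside 746 that were higher, where chance gives 801 of the 16011 genes in all. The lower genes of smallest p, none past the threshold, were Vwa1 (log2 fold change -2.67, adjusted p = 0.0603), Nr4a1 (-2.73, 0.0606), Icosl (-2.29, 0.0606), Elmo2 (-2.40, 0.0606) and Slc1a5 (-2.33, 0.0606). DESeq2 called 122 genes higher and 312 lower, and limma voom with sample weights called 249 and 577. RLE size factors gave 7 higher and 1 lower. Groups did not overlap for 19.5% of genes, where chance gives 10%. Cthrc1 and Timp1 stayed past the threshold whichever of the 11 libraries was left out. Spp1 lost it without sham day 7 replicate 2 (adjusted p = 0.0549), as did Adam12, Ckap2 and Mki67 at the same value. Adam12 lost it as well without sham day 7 replicate 3 (0.0827), PNX day 7 replicate 3 (0.0701) or PNX day 14 replicate 2 (0.0552); Mki67 without PNX day 7 replicate 1 (0.128), PNX day 14 replicate 2 (0.0654) or replicate 3 (0.0703); and Ckap2 without sham day 7 replicate 3, any 1 of the 3 PNX libraries of day 7, or PNX day 14 replicate 2 or 3 (0.0544 to 0.112). The count of higher genes was 39 without sham day 7 replicate 1, 10 without sham day 7 replicate 3, 14 without PNX day 7 replicate 2, 27 and 26 without sham day 14 replicate 1 and 2, and 3 without sham day 7 replicate 2 or PNX day 14 replicate 2. The count of lower genes was 386 without sham day 7 replicate 1, 56 and 68 without sham day 14 replicate 1 and 2, and at most 2 without any other library. With the background on olfactory and vomeronasal genes as a covariate, Cthrc1 (4.10 ± 0.42, adjusted p = 0.00136) and Timp1 (2.43 ± 0.28, adjusted p = 0.00223) passed. Spp1 (4.78 ± 0.90, 0.146), Adam12 (3.29 ± 0.56, 0.0878), Ckap2 (2.91 ± 0.51, 0.0878) and Mki67 (2.56 ± 0.48, 0.108) did not. The same 4 lost the call with the GC offset: Spp1 (5.15 ± 0.83, 0.0691), Adam12 (3.57 ± 0.58, 0.0551), Ckap2 (2.90 ± 0.51, 0.0628) and Mki67 (2.65 ± 0.48, 0.0657). With the GC offset and the replicate block Adam12 (0.0720), Ckap2 (0.0891) and Mki67 (0.118) lost it. Ckap2 and Mki67 lost it with the replicate block (each 0.0510), in the test against a fold of 1.5 (each 0.0862) and without the 3 libraries of highest background (0.144 and 0.106). With only the groups compared Ckap2 (0.0550), Mki67 (0.0931) and Spp1 (0.101) lost it. With total counts Spp1 lost it (0.0527).

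Genes of cell division rose together at day 7. Of the 40 members of the proliferation list, 36 were higher and 4 lower after PNX; 1 passed over all genes and 18 passed adjusted over the list alone, all higher (median log2 fold change 1.39; camera, preset correlation, adjusted p = 6.76e-20; adjusted p = 0.140 with an estimated correlation). Examples are the mitotic genes Ccnb2 (2.57 ± 0.50, adjusted p over the list alone 0.00135), Tpx2 (2.01 ± 0.43, 0.00279) and Cenpe (2.33 ± 0.53, 0.00285). The list of fibrosis-associated activated fibroblasts rose as well: 15 of 18 members were higher, 3 passed over all genes and 5 over the list alone (median 0.96, adjusted p = 8.34e-11; adjusted p = 0.0841 with an estimated correlation). Besides Spp1, Cthrc1 and Adam12, it holds Tnc, the matrix glycoprotein tenascin C, at 29.0 CPM in sham and 177 CPM in PNX (2.61 ± 0.52, 0.000479 over the list alone), and Runx1 (1.37 ± 0.37, 0.00629). Inflammatory cytokines and acute phase genes rose, with 19 of 24 members higher, 0 past over all genes and 2 over the list alone, Cxcl5 (3.06 ± 0.65) and Cxcl10 (1.47 ± 0.43) (median 0.73, adjusted p = 2.38e-05; adjusted p = 0.140 with an estimated correlation). Interferon response genes rose too, with 19 of 24 higher, 0 past over all genes and 4 over the list alone: Oas1a, Isg15, Zbp1 and Ifi44 (median 0.64, adjusted p = 1.29e-04; adjusted p = 0.565 with an estimated correlation). The interferon call was lost without PNX day 7 replicate 3 (adjusted p = 0.151).

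Markers of resident fibroblasts fell at day 7. All 16 alveolar fibroblast genes were lower, 0 past the threshold over all genes and 6 adjusted over the list alone (median -0.88, adjusted p = 1.32e-08; adjusted p = 0.149 with an estimated correlation). Among them, the integrin gene Itga8 went from 1037 to 347 CPM (-1.58 ± 0.50), the growth factor receptor gene Fgfr4 from 22.4 to 7.99 CPM (-1.48 ± 0.44), the amino acid transporter gene Slc7a10 by -1.72 ± 0.35 and the transcription factor gene Tcf21 by -1.18 ± 0.36. Adventitial fibroblast genes fell, with 15 of 18 lower and 6 past over the list alone (median -1.10, adjusted p = 2.81e-06; adjusted p = 0.374 with an estimated correlation); Pi16 stood at 4621 CPM in sham and 936 CPM in PNX (-2.30 ± 0.61). Hedgehog targets fell, with 8 of 9 lower and 4 past over the list alone, Ptch1 (-2.10 ± 0.49), Foxl1 and Gli1 among them (median -0.94, adjusted p = 0.00204; adjusted p = 0.275 with an estimated correlation). The Wnt target list was called as lower, with 14 of 15 members lower and 0 past over the list alone (median -0.67, adjusted p = 0.00568; adjusted p = 0.140 with an estimated correlation). Circadian clock genes fell, with 15 of 16 lower and 4 past over the list alone, Cry2, Arntl, Cry1 and Npas2 (median -0.42, adjusted p = 0.00568; adjusted p = 0.140 with an estimated correlation). Immediate early and dissociation stress genes, which respond within minutes to handling of cells, were split: 15 of 25 were lower, with 10 past as lower and 2 as higher over the list alone (median -0.93, adjusted p = 1.28e-05; adjusted p = 0.221 with an estimated correlation). Junb stood at 6790.3 CPM in sham and 540 CPM in PNX (-3.65 ± 0.76), and Egr1 at 3682 and 909 CPM (-2.02 ± 0.40). None of the 10 lists called at day 7 held with an estimated correlation, and 6 of the 10 splits of the 6 libraries, the real one included, called at least 10 lists with the preset one.

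At day 14, the same comparison asked which differences were present later. Angptl7, which encodes a secreted angiopoietin-like protein, was the only gene past the threshold. It rose from 57.9 ± 22.0 CPM in 2 sham libraries to 1306 ± 554 CPM in 3 PNX libraries (log2 fold change 4.49 ± 0.66, adjusted p = 0.0390 by edgeR) and lies on chromosome 4 (148495183 to 148500460). Higher but not past the threshold were Wt1, the Wilms tumour transcription factor of mesothelium, at 17.8 and 258 CPM (3.85 ± 0.65, adjusted p = 0.0652), Map3k1 (2.96, 0.0652), Cthrc1 at 20.6 and 117 CPM (2.53 ± 0.46, 0.0666) and Gas7 (2.52, 0.0666). Lower but not past it were Tsc22d3, a gene induced by glucocorticoids, at 585 and 90.6 CPM (-2.69 ± 0.43, 0.0540), Colq (-3.09, 0.0652), the chemokine gene Cxcl9 (-3.36, 0.0666), the interferon-induced Ifi27l2a (-2.21, 0.0666) and Mzb1, a plasma cell gene (-5.75, 0.0666). The count of lower genes was 0 with edgeR, 45 with DESeq2 and 0 with limma voom, and 581 were lower at an unadjusted p under 0.05; higher genes numbered 63 with DESeq2, 0 with voom and 510 at the unadjusted threshold. RLE size factors gave 1 higher and 1 lower, and total counts without TMM factors 2 and 1. Groups did not overlap for 17.9% of genes, where chance gives 20% for 2 against 3.

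The Angptl7 call was lost without sham day 14 replicate 1 (adjusted p = 0.146), PNX day 14 replicate 2 (0.245) or PNX day 14 replicate 3 (0.252). It was also lost with the X and Y covariate (4.35 ± 0.70, 0.0693), with the replicate block (4.22 ± 0.68, 0.0605), in the test against a fold of 1.5 (0.0560) and with limma voom (0.148). Among libraries with Y-linked counts, where each group of day 14 keeps 1 library, assumed to vary like the others, Angptl7 did not pass (3.41 ± 0.94, adjusted p = 1). The 1 gene that did was another. Without sham day 14 replicate 2, 60 genes passed as higher, Angptl7 among them (5.10 ± 0.94), and 14 as lower. Without sham day 7 replicate 2 there were 13 and 12, without sham day 7 replicate 3 7 and 11, without sham day 14 replicate 1 2 and 9, and without each of the other libraries at most 7 and 4. With the background covariate 23 and 12 passed.

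The extracellular matrix list was called as higher at day 14 after PNX: all 35 members were higher, 0 past the threshold over all genes and 0 adjusted over the list alone (median 0.70, adjusted p = 6.83e-14; adjusted p = 0.337 with an estimated correlation). Col3a1 stood at 1909.7 CPM in sham and 4299 CPM in PNX (1.17 ± 0.45), Col5a2 at 194 and 441 CPM (1.18 ± 0.40), and Fbln2 at 70.5 and 190 CPM (1.42 ± 0.50). Col1a1 stood at 763 CPM in sham and 1735 CPM in PNX, and at day 7 at 3802 and 2253 CPM. The list of fibrosis-associated activated fibroblasts rose, with 16 of 18 higher and 4 past over the list alone: Cthrc1, the growth factor Pdgfc (1.79 ± 0.53), Spp1 (2.14 ± 0.72) and the activin subunit Inhba (1.47 ± 0.51) (median 0.98, adjusted p = 6.07e-10; adjusted p = 0.0745 with an estimated correlation). The smooth muscle and contractile list was called as higher, with 15 of 16 members higher and 0 past over the list alone (median 0.55, adjusted p = 5.03e-05; adjusted p = 0.337 with an estimated correlation). Myh11 stood at 207 and 522 CPM. Between days after sham the matrix, smooth muscle and mesothelial lists were called as lower. Between days after PNX only the smooth muscle list of these was called, as higher. The sham libraries of day 14 also stood highest in haematopoietic markers. An effect of PNX on these lists therefore cannot be told apart from a difference in those sham libraries. Mesothelial genes rose, with 13 of 14 higher and 1 past over the list alone, Wt1 (median 0.87, adjusted p = 1.07e-06; adjusted p = 0.535 with an estimated correlation), but not without sham day 14 replicate 1 (adjusted p = 0.0601). Alveolar fibroblast genes fell, with 13 of 16 lower and 5 past over the list alone: Slc7a10 (-1.95 ± 0.38), Fgfr4 (-2.37 ± 0.48), Wnt2 (-1.38 ± 0.38), Ces1d and Tcf21 (median -0.70, adjusted p = 2.14e-06; adjusted p = 0.337 with an estimated correlation). Without sham day 14 replicate 2 that list turned direction (adjusted p = 0.950).

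Haematopoietic markers fell at day 14, although CD45-positive cells had been gated out: all 25 were lower, 0 past over all genes and 11 over the list alone (median -2.14, adjusted p = 2.95e-19; adjusted p = 0.0920 with an estimated correlation). Laptm5 stood at 29.7 CPM in sham and 3.54 CPM in PNX (-3.06 ± 0.60), Ctss at 102 and 21.9 CPM (-2.21 ± 0.54), and S100a8 at 14.2 and 1.12 CPM (-3.62 ± 0.75). The immediate early and dissociation stress list was called as lower, with 23 of 25 members lower and 0 past over the list alone (median -0.49, adjusted p = 0.00636; adjusted p = 0.591 with an estimated correlation), and turned direction without sham day 14 replicate 2 (adjusted p = 0.950). The Schwann and neural list was called as lower, with 8 of 9 members lower and 0 past over the list alone (median -0.82, adjusted p = 0.0406; adjusted p = 0.337 with an estimated correlation), a call lost in 6 of the 11 refits without 1 library (adjusted p from 0.0530 to 0.355). Those were the refits without sham day 7 replicate 2, PNX day 7 replicate 1, either sham library of day 14, or PNX day 14 replicate 1 or 2. The proliferation list was not past the threshold at day 14, with 15 members higher and 25 lower (adjusted p = 0.0952).

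**Figure D2:**
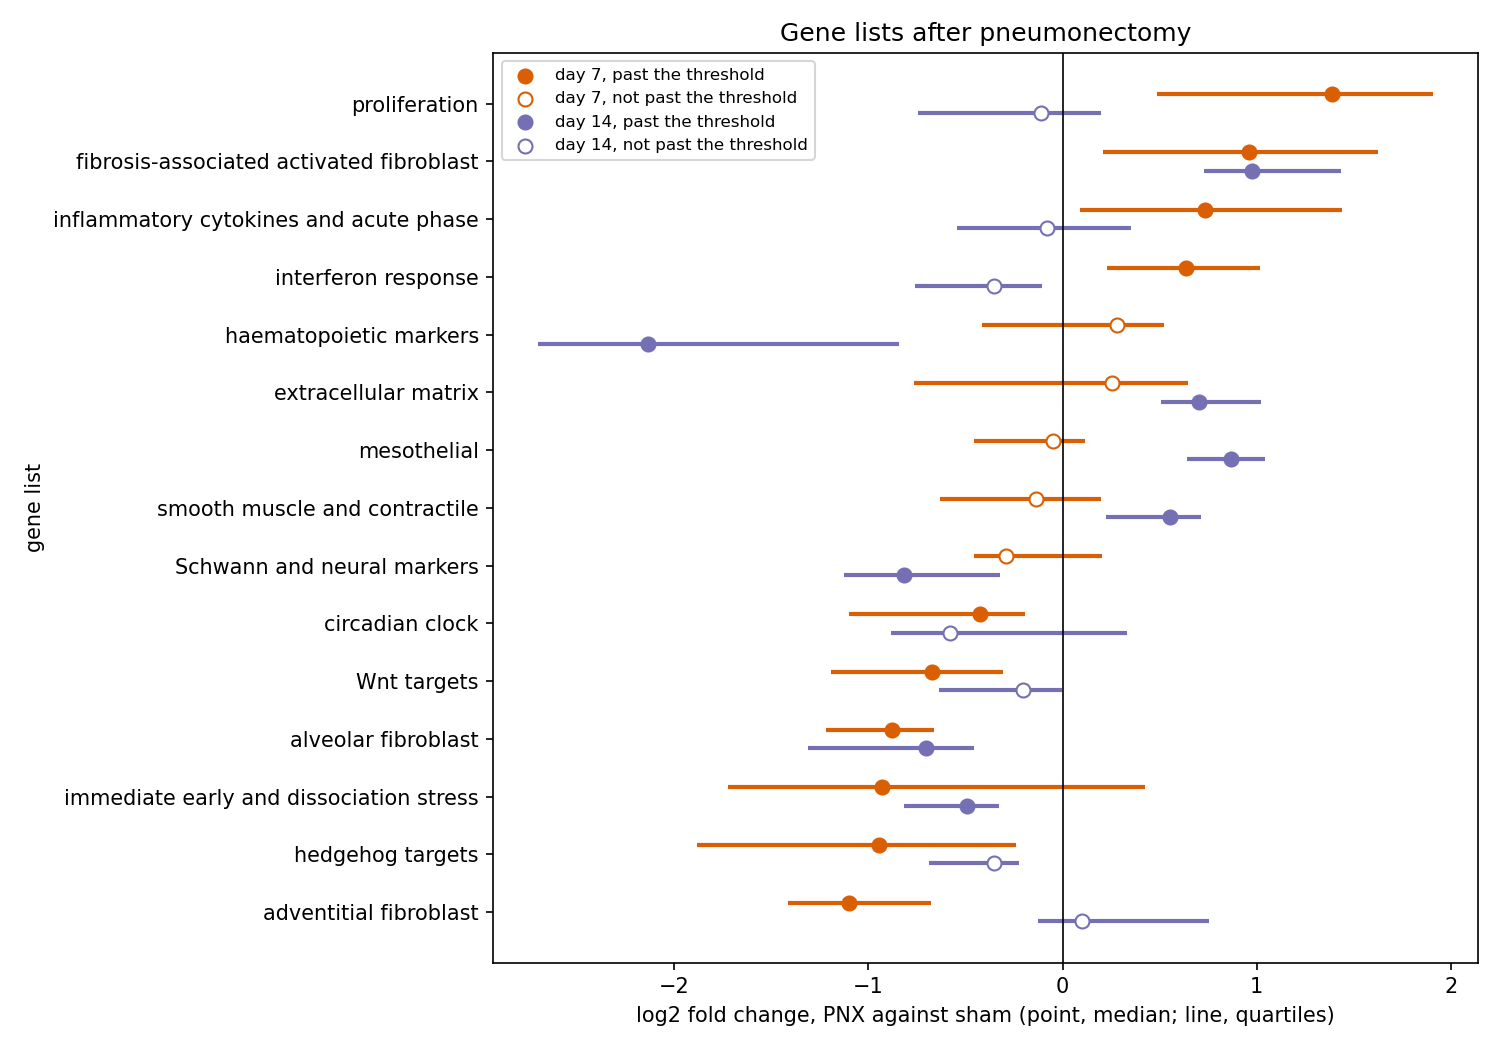
Median log2 fold change (PNX against sham) of the members of each gene list past the threshold at day 7 or day 14, with a line from the lower to the upper quartile. Filled points passed the threshold with the preset correlation and open points did not; the proliferation list stood at 1.39 at day 7 and -0.11 at day 14, and the fibrosis-associated list at 0.96 and 0.98.

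Of the lists not past the threshold at either day, the adjusted p at day 7 and day 14 was 0.312 and 0.383 for lipofibroblast and lipid droplet genes, 0.184 and 0.173 for alveolar myofibroblast genes, 0.662 and 0.312 for pericyte genes, and 0.504 and 0.333 for secreted niche ligands. It was 0.0856 and 0.805 for BMP targets, 0.149 and 0.938 for YAP and SRF targets, 0.966 and 0.496 for retinoid genes, 0.847 and 0.715 for hypoxia and glycolysis, 0.325 and 0.727 for cholesterol synthesis, and 0.894 and 0.755 for the unfolded protein response. Among markers of other cell types it was 0.662 and 0.805 for epithelial, 0.0507 and 0.280 for endothelial, 0.0679 and 0.639 for erythroid and platelet, 0.566 and 0.312 for cardiac and skeletal muscle, and 0.229 and 0.218 for chondrocyte markers. The epithelial list had a median of -0.95 at day 7 while its test pointed up, and without sham day 7 replicate 3 it pointed down and passed (adjusted p = 1.65e-05). Mitochondrially encoded genes were absent from the table.

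Genes fixed in advance for their role in the alveolar niche stayed under the threshold at both days, Mki67 at day 7 apart. The log2 fold change at day 7 and day 14 was -0.81 and -0.50 for Fgf10, the growth factor of lung outgrowth, -1.09 and -0.64 for Pdgfra, -0.99 and 0.91 for Pdgfrb, and -0.60 and -1.38 for Wnt2. Eln, the elastin gene, gave 0.40 and 1.47, Col1a1 -0.75 and 1.19, and Acta2, the actin of contractile cells, 0.03 and 0.77. The lipid droplet gene Plin2 gave 0.03 and -0.36 and Pparg 0.16 and -0.85. Among genes of Wnt, hedgehog and FGF signalling, the values were -0.59 and -0.20 for Axin2, -1.59 and -0.35 for Gli1, -0.14 and 0.67 for Lgr5, -0.58 and -1.31 for Lgr6, -0.46 and -0.28 for Fgf7 and 0.36 and 0.30 for Fgf18. The markers of gated-out cells gave 0.08 and -0.68 (Epcam), -1.01 and -1.39 (Ptprc, which encodes CD45), 1.55 and 0.42 (Pecam1, which encodes CD31) and 1.03 and -1.42 (Hopx). Adjusted p for the genes named here lay between 0.255 and 0.979 with edgeR at both days.

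Averaged over both days, PNX was compared with sham to find genes that differed in the mean. A gene can pass this test through a change on 1 day alone. 22 genes rose and 9 fell. Cthrc1 rose by 3.32 ± 0.32 on the log2 scale (adjusted p = 8.02e-05, edgeR), Spp1 by 3.60 ± 0.52 (0.0105), the elastase gene Cela1 by 3.54 ± 0.57 (0.0105) and Npl, an enzyme of sialic acid breakdown, by 3.25 ± 0.51 (0.0105). Calca, the precursor gene of calcitonin and CGRP, passed as higher (adjusted p = 0.0277); it had 3 counts in the sham libraries of day 7 and 304 in those of PNX, a ratio of count shares of 126 (95% exact Poisson interval 42.6 to 612, for counting error only). At day 14 it had 5 and 849 counts, a ratio of 108 (46.3 to 335). Of the genes that fell, Colq, which encodes the collagen tail of acetylcholinesterase, went from 28.5 to 5.29 CPM at day 7 and from 27.0 to 3.18 CPM at day 14 (-2.75 ± 0.35, adjusted p = 0.00284). Bcl2l1, which encodes the survival protein Bcl-xL, fell (-2.00 ± 0.35, 0.0174), as did Fgfr4 (-1.92 ± 0.33, 0.0137), Slc7a10 (-1.83 ± 0.26, 0.00546) and the transcription factor Klf15 (-1.71 ± 0.30, 0.0204). The naming rule required that in each of these 10 genes every PNX library lay on the same side of every sham library of its day. Adam12, Ncam1, Ildr2, Laptm5 and Tsc22d3 were among the called genes that did not meet it. Colq overlaps the predicted gene Gm49387 and Slc7a10 overlaps Lrp3 on the opposite strand, and the strand used for counting was not stated.

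Cthrc1, Colq and Slc7a10 passed whichever library was left out. Of the other named genes, Bcl2l1, Fgfr4, Klf15, Cela1 and Npl lost the call without sham day 14 replicate 2 (adjusted p = 0.0718 to 0.101) or PNX day 14 replicate 2 (0.0612 to 0.111). Bcl2l1, Fgfr4 and Klf15 also lost it without PNX day 14 replicate 3 (0.0728 to 0.0994), and Klf15 without sham day 7 replicate 3 (0.0568) or PNX day 7 replicate 1 (0.0639). Spp1 lost it without sham day 14 replicate 1 (0.104) or 2 (0.113), and its log2 fold change was 2.98 without PNX day 7 replicate 2. Without PNX day 7 replicate 3 that of Cela1 was 2.90, of Npl 2.61 and of Calca 5.86 in place of 6.52. Calca lost it without sham day 7 replicate 2 (0.0942) or 3 (0.0901), PNX day 7 replicate 2 (0.0619), sham day 14 replicate 1 (0.105) or 2 (0.187), or PNX day 14 replicate 3 (0.0609). The 31 genes became 8 without PNX day 14 replicate 2, 13 without PNX day 14 replicate 3, 10 without sham day 14 replicate 2, 127 without sham day 14 replicate 1, 74 without PNX day 14 replicate 1 and 192 without sham day 7 replicate 1. They became 2 in the 7 libraries with Y-linked counts, where Cthrc1 kept its call and the other 30 lost theirs. They became 77 with the background covariate, where Bcl2l1 (0.0531) and Spp1 (0.0665) were among the 4 lost. With the replicate block 18 of the 31 kept their call, and Bcl2l1 (0.0721), Fgfr4 (0.0518) and Klf15 (0.0583) did not. These 3 lost it as well with the GC offset and the block (0.0673 to 0.0736) and, with Calca (0.0553), in the test against a fold of 1.5 (0.0837 to 0.141). Without the 3 libraries of highest background Bcl2l1 (0.0586), Klf15 (0.0718) and Calca (0.222) lost it. Without a filter Calca lost it (0.0641). With limma voom Bcl2l1, Klf15 (each 0.105) and Fgfr4 (0.154) lost it, as did Npl (2.66, 0.413), Cela1 (2.86, 0.523) and Calca (5.11, 0.568). Total counts without TMM factors gave 28 higher and 22 lower.

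The list of fibrosis-associated activated fibroblasts was the only one of the 14 lists called for the mean of both days that held with an estimated correlation. Of its 18 members 17 were higher, 3 past the threshold over all genes and 10 over the list alone (median log2 fold change 1.01; camera adjusted p = 3.57e-19; adjusted p = 0.0136 with an estimated correlation). Alveolar fibroblast genes fell, with 15 of 16 lower, 2 past over all genes (Fgfr4 and Slc7a10) and 9 over the list alone (median -0.93, adjusted p = 1.02e-13; adjusted p = 0.171 with an estimated correlation). The other lists called were extracellular matrix, proliferation, mesothelial, endothelial and inflammatory genes as higher, and haematopoietic, immediate early, hedgehog target, circadian, adventitial fibroblast, Schwann and Wnt target genes as lower. Their adjusted p with an estimated correlation lay between 0.200 and 0.707. At the preset correlation 7 of them lost the call without 1 library. Endothelial genes did so without sham day 7 replicate 1 (adjusted p = 0.128) or 3 (0.191), PNX day 7 replicate 1 (0.637), sham day 14 replicate 2 (0.0937) or PNX day 14 replicate 3 (0.0543). Adventitial fibroblast genes did so without sham day 7 replicate 1 (0.0755) or 3 (0.142), sham day 14 replicate 2 (0.615) or PNX day 14 replicate 2 (0.0513). Wnt target genes did so without sham day 7 replicate 3 (0.142), PNX day 7 replicate 2 (0.0660), sham day 14 replicate 2 (0.431) or PNX day 14 replicate 1 (0.0916). The call for inflammatory genes was lost without sham day 7 replicate 1 (0.129), PNX day 7 replicate 1 (0.0925), sham day 14 replicate 1 (0.408) or PNX day 14 replicate 2 (0.0513). Mesothelial genes lost theirs without sham day 7 replicate 2 (0.237), PNX day 7 replicate 3 (0.101) or sham day 14 replicate 1 (0.408). Schwann genes lost theirs without sham day 7 replicate 3 (0.0567), sham day 14 replicate 1 (0.253) or PNX day 14 replicate 2 (0.0513). Circadian genes lost theirs without sham day 14 replicate 2 (0.162). The day 7 and day 14 fold changes, from separate libraries, correlated across genes at r = -0.11, where genes are not independent replicates. At an unadjusted p under 0.05, 68 genes were higher at both days and 79 lower at both, where independent lists give 23.8 and 46.9. Of the rest, 62 were higher at day 7 and lower at day 14, where they give 27.1, and 15 were lower at day 7 and higher at day 14, where they give 41.2. The p-values of both days share 1 estimate of each gene's spread, so a gene of small spread can pass at both. Independent lists are therefore not a proper expectation, and no conclusion is drawn from these counts.

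**Figure D3:**
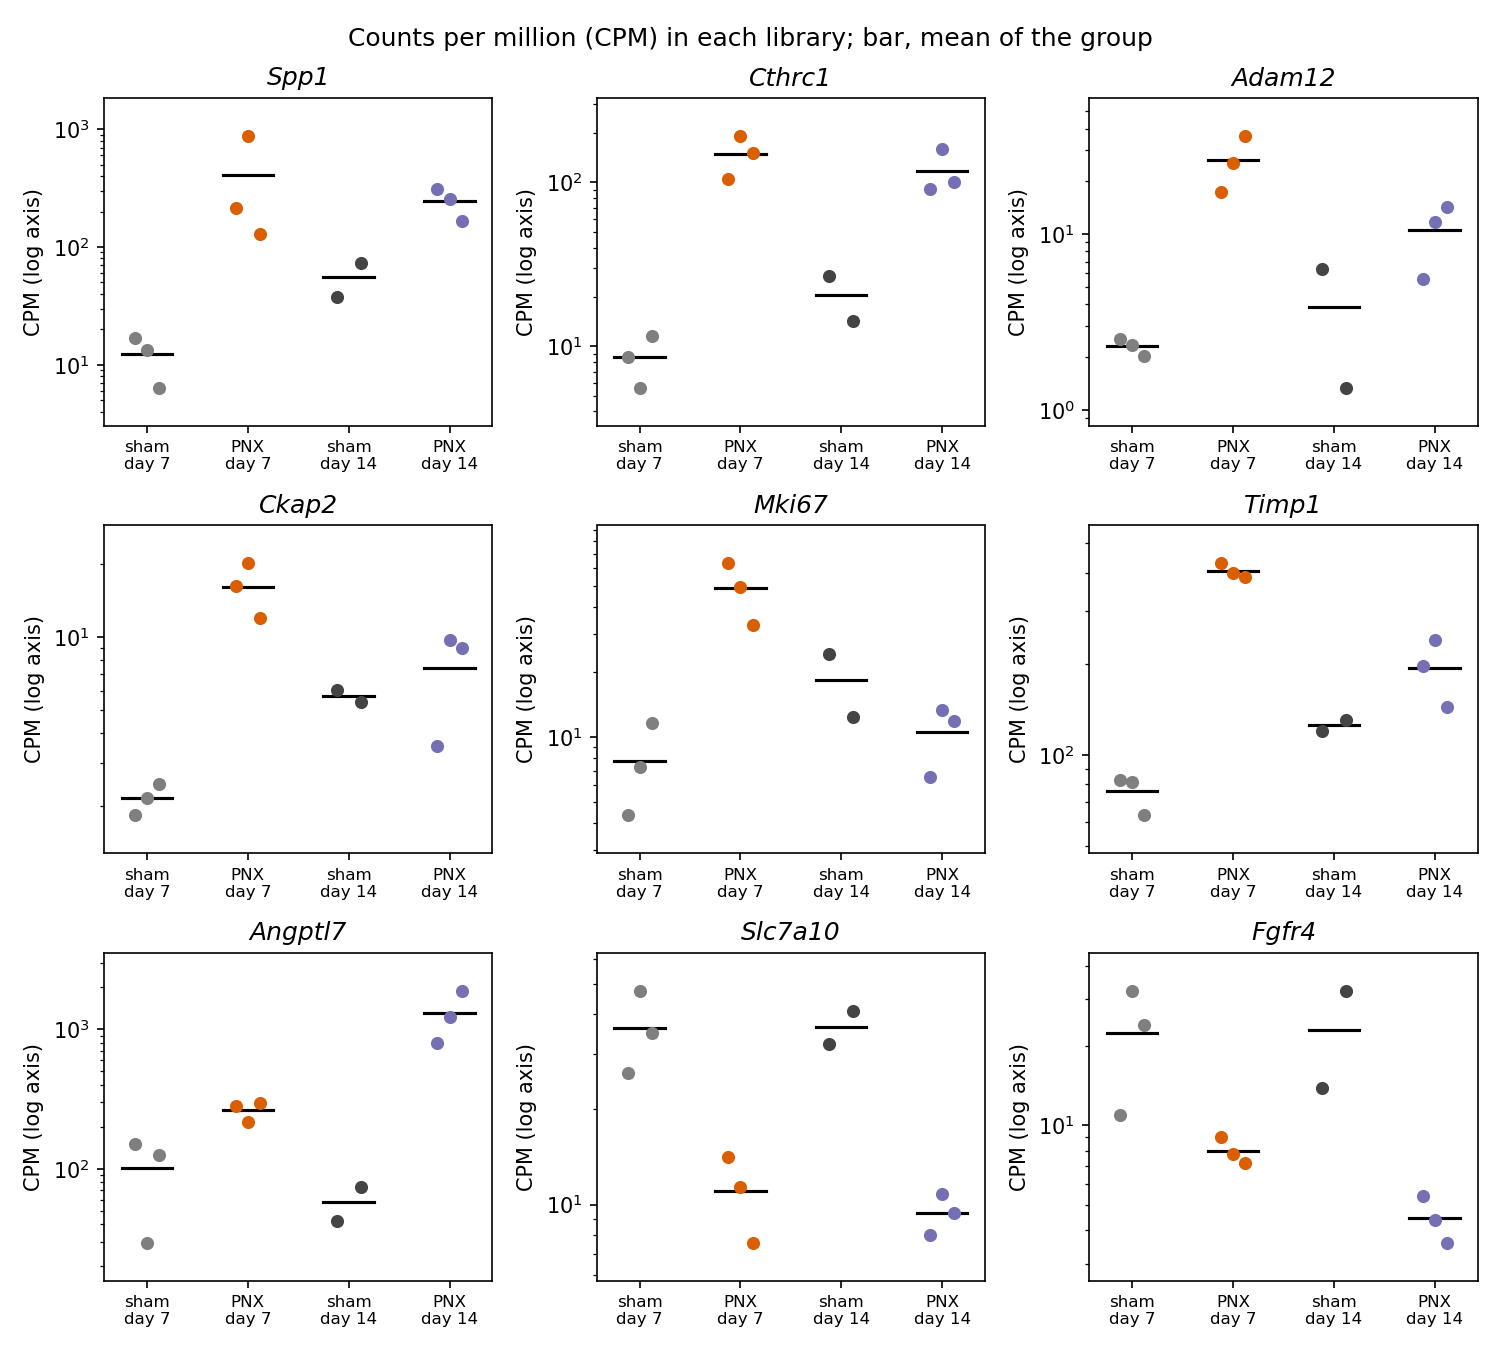
CPM (log axis) in each library by group for the 7 genes past the threshold at day 7 or day 14, and for Slc7a10 and Fgfr4, which passed for the mean of both days; bars give the group means. Cthrc1 averaged 8.59 and 20.6 CPM in the sham groups and 150 and 117 CPM after PNX.

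Whether the PNX effect itself differed between the days was tested by the interaction. No gene passed with edgeR; 1402 genes had an unadjusted p under 0.05, DESeq2 called 93 and limma voom 0. The genes of smallest p, none past the threshold, had effects more positive at day 14 for Map3k1 (3.67 ± 0.65, adjusted p = 0.160), Gas7 (3.22, 0.160), Wt1 (3.73, 0.203), Dpysl2 (2.62, 0.203) and H1f0 (2.55, 0.204). Effects were more negative at day 14 for Ifi27l2a (-3.64 ± 0.56, 0.0724), Mki67 (-3.41 ± 0.63, 0.160), Cfd (-5.11, 0.168), Cks2 (-3.63, 0.168) and S100a9 (-4.72, 0.168). By lists, the effect on proliferation genes was lower at day 14 for 36 of 40 members, with 14 past over the list alone (median difference -1.58, adjusted p = 1.07e-15; adjusted p = 0.323 with an estimated correlation). That on haematopoietic markers was lower for 23 of 25, with 7 past over the list alone (median -1.39, adjusted p = 2.31e-12; adjusted p = 0.238 with an estimated correlation). Without sham day 14 replicate 2, 370 genes passed, without sham day 7 replicate 2 13 did, and without any other library at most 5.

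After PNX, day 14 was compared with day 7, between libraries whose GC correlation was -0.38 to -0.32 at day 14 and -0.17 to 0.31 at day 7. No gene passed with edgeR; 1096 had an unadjusted p under 0.05, DESeq2 called 63 and limma voom 111. Proliferation genes fell, with 39 of 40 members lower at day 14 and 24 past over the list alone (median -1.59, adjusted p = 1.84e-31; adjusted p = 0.400 with an estimated correlation). Mki67 stood at 48.5 CPM at day 7 and 10.6 CPM at day 14 (-2.19 ± 0.43, adjusted p = 0.186), Tpx2 at 34.9 and 5.86 CPM (-2.57 ± 0.45) and Aurka at 10.5 and 1.17 CPM (-3.10 ± 0.63), both at 0.186. Also lower, not past the threshold, were the adipsin gene Cfd (-3.87, 0.186) and D17H6S56E-5 (-2.57, 0.186), and higher were Angptl7 (2.30, 0.231), the basement membrane collagen gene Col4a3 (2.56, 0.186), Map3k1 (2.15, 0.186), Il12b (2.92, 0.186) and Dpep2 (2.41, 0.186). Smooth muscle (13 of 16 higher, adjusted p = 0.00421), alveolar myofibroblast (11 of 16, 0.0107) and epithelial marker lists (14 of 18, median 1.76, 4.41e-06) were called as higher, with 0 members past over the list alone, each at adjusted p = 0.791 with an estimated correlation. The interferon response list (20 of 24 lower, 1 past over the list alone, adjusted p = 0.0107) and the immediate early list (20 of 25, 0 past, 0.0401) were called as lower, both at adjusted p = 0.912 with an estimated correlation. The interferon call was lost without PNX day 7 replicate 3 (0.816) or PNX day 14 replicate 1 (0.674), and the immediate early call without PNX day 7 replicate 2 (0.0954) or PNX day 14 replicate 2 (0.0916) or 3 (0.133).

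After sham surgery, leukocyte genes were higher at day 14 than at day 7. Ccl6, a myeloid chemokine gene, rose from 10.8 ± 7.32 to 153 ± 18.3 CPM (log2 fold change 3.84 ± 0.48, adjusted p = 0.00434 by edgeR), Cybb, the phagocyte oxidase subunit, from 5.80 ± 3.39 to 49.1 ± 8.67 CPM (3.10 ± 0.48, 0.0359) and Cd53, a leukocyte surface gene, from 4.79 ± 1.64 to 42.9 ± 11.8 CPM (3.18 ± 0.51, 0.0431). Haematopoietic markers rose, with 23 of 25 higher, 0 past over all genes and 17 over the list alone (median 2.13, adjusted p = 6.60e-22; adjusted p = 0.0693 with an estimated correlation). Examples from the lists below were chosen after their values were seen. Inflammatory genes rose, with 19 of 24 higher and 7 past over the list alone, Cxcl1, Il6, Ccl8 and Ccl7 among them (median 0.71, adjusted p = 6.86e-06; adjusted p = 0.0939 with an estimated correlation). Extracellular matrix genes fell, with 31 of 35 lower and 6 past over the list alone, Col1a1 from 3802 to 763 CPM (-2.32 ± 0.63) among them (adjusted p = 4.05e-07; adjusted p = 0.654 with an estimated correlation). Adventitial fibroblast, mesothelial, immediate early, Wnt target and smooth muscle genes were also called lower, and epithelial and interferon genes higher (adjusted p from 0.269 to 0.857 with an estimated correlation). Below the threshold, Fcer1g (3.15, adjusted p = 0.0626) and Ifi27l2a (2.33, 0.0695) were higher and Gas7 (-2.80, 0.0543), Spryd3 (-2.65, 0.0975), Man2c1 (-2.64, 0.0975), Lrrc16a (-2.51, 0.0975) and Slc1a5 (-2.47, 0.0975) lower.

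This comparison had 2 sham libraries at day 14. Without replicate 1 of them, the calls for extracellular matrix, adventitial fibroblast and immediate early genes were lost (each at adjusted p = 0.234), as were those for mesothelial (0.203), smooth muscle (0.320), Wnt target (0.253) and epithelial genes (0.253). Without replicate 2, those for inflammatory (0.0778) and interferon genes (0.246) were lost, and 958 genes passed. The call for smooth muscle genes was also lost without sham day 7 replicate 1 (0.139), for interferon genes without sham day 7 replicate 2 (0.223) and for Wnt target genes without sham day 7 replicate 3 (0.0728). Ccl6 kept its call without any 1 of the 11 libraries; Cybb and Cd53 lost theirs without sham day 7 replicate 3 (0.154 and 0.169) or any 1 of the 3 PNX libraries of day 14 (0.0647 to 0.113), which are not among the libraries compared. Without sham day 7 replicate 1, 545 genes passed, without sham day 7 replicate 2 29, without sham day 14 replicate 1 11 and without PNX day 7 replicate 3 6. With the replicate block (0.119 and 0.127), the background covariate (each 0.0587), the stricter filter (each 0.0516) and the fold of 1.5 (0.0899 and 0.0992), Cybb and Cd53 lost their calls. With the GC offset Ccl6, Cybb (each 0.0674) and Cd53 (0.0679) lost theirs. They also did so in the libraries with Y-linked counts (0.260 to 0.751). Total counts without TMM factors, only the sham groups in the fit, the GC offset, and limma voom each gave 0 genes, where 2283 had an unadjusted p under 0.05.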

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

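In this part the tests of the interaction, the fits without 1 library and the counts over other splits were planned; the tests by marker lists of other cell types, the X and Y covariate, the libraries with Y-linked counts the background covariate and the GC offset were chosen only after the results they concern had been seen. The PNX effect of 9 gene lists differed between day 14 and day 7 by a test of the interaction at the preset correlation. Of these, proliferation (adjusted p = 1.07e-15), haematopoietic (2.31e-12), inflammatory (6.48e-05) and interferon genes (9.64e-05) had a lower effect at day 14, at 0.323, 0.238, 0.238 and 0.636 with an estimated correlation. Adventitial fibroblast (5.91e-05), mesothelial (6.48e-05), smooth muscle (6.48e-05), extracellular matrix (6.48e-05) and alveolar myofibroblast genes (0.0423) had a higher effect, at 0.636, 0.636, 0.323, 0.636 and 0.636 with an estimated correlation. The matrix call was lost without sham day 14 replicate 1 (0.336), the inflammatory call without sham day 14 replicate 2 (0.138), the interferon call without PNX day 7 replicate 3 (0.0507) or sham day 14 replicate 2 (0.977). The myofibroblast call was lost without sham day 7 replicate 1 (0.201), PNX day 7 replicate 1 (0.0657) or 2 (0.0551), sham day 14 replicate 1 (0.318) or PNX day 14 replicate 2 (0.157). No group has 4 or more libraries, so single libraries were not tested for standing apart. The 2 sham libraries of day 14 correlated with each other at r = 0.87 in log2 CPM, and the other pairs within a group at 0.92 to 0.96.

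Spp1, Cthrc1, Adam12, Ckap2, Mki67 and Timp1 were higher after PNX at day 7. Macrophages, which express Spp1 and which the CD45 gate removes, would bring their other transcripts, yet 26 macrophage markers (9 of them above 10 CPM in each group, 9 in the haematopoietic list) had a median log2 fold change of -0.12, with quartiles of -0.56 and 0.48, against at least 3.65 needed for Spp1. In PNX libraries Lyz2 averaged 81.0, Ctss 14.4 and Tyrobp 2.22 CPM beside 409 for Spp1. Trem2, however, went from 1.62 to 16.9 CPM, at 15.1, 5.26 and 30.2 CPM in the 3 PNX libraries where Spp1 stood at 216, 881 and 130 CPM. Cd14 (38.2 and 119 CPM in sham and PNX), Chil3 (17.3 and 41.6) and Mrc1 (4.25 and 11.9) were higher as well. Gpnmb (67.7 and 32.1 CPM), Cd9 (411 and 379) and Lgals3 (99.8 and 91.2) were not higher, from levels that would hide a small share. A change of state in few macrophages is therefore not excluded. Sex was unequal between libraries, and with a covariate for X and Y transcripts 6 of the 6 genes passed, whereas in the 7 libraries with Y-linked counts 1 of 6, Cthrc1, passed (adjusted p = 0.0326) and Timp1 (0.0672; log2 fold change 2.26 ± 0.32 against 2.42 ± 0.32 in all libraries), Adam12 (0.0684; 3.38 ± 0.49 against 3.51 ± 0.55), Mki67 (0.0687; 3.03 ± 0.44 against 2.64 ± 0.44), Ckap2 (0.101; 2.97 ± 0.49 against 2.89 ± 0.48) and Spp1 (0.222; 4.70 ± 0.93 against 5.06 ± 0.70) did not, each within 1 standard error of its value in all 11. Of 10 splits of the 6 libraries, too few for a share under 0.05, 2, the real one included, gave at least as many genes. The highest other gave 99 by parting the libraries at a total of 5417105 to 7378207 counts. That split also parted them by endothelial markers (at most 3.50 log2 CPM in the deeper libraries, at least 5.09 in the others). It parted them by haemoglobin as well (at most 1.78% and at least 2.90% of counts). Depth therefore cannot be told apart from cells carried through the sort as the structure behind it. With the background covariate Cthrc1 and Timp1 passed and the other 4 did not (adjusted p = 0.0878 to 0.146). The fold changes of these 4 lay within 1 standard error of those without it (Spp1 4.78 ± 0.90 against 5.06 ± 0.70, Adam12 3.29 ± 0.56 against 3.51 ± 0.55, Ckap2 2.91 ± 0.51 against 2.89 ± 0.48, Mki67 2.56 ± 0.48 against 2.64 ± 0.44). Their standard errors were larger, as with the GC offset (0.0551 to 0.0691).

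Krt18, Dmkn, Anxa8 and Gjb5, chosen after their values were seen, were higher after PNX in the mean of both days; Gjb5 kept its call without any 1 library, and Anxa8, Dmkn and Krt18 lost theirs without sham day 14 replicate 2 (adjusted p = 0.0691 to 0.101) or PNX day 14 replicate 2 (0.0745 to 0.0851), Dmkn and Krt18 without PNX day 14 replicate 3 (0.0848 and 0.0654) or PNX day 7 replicate 1 (0.0501), and Dmkn without sham day 7 replicate 3 (0.0582), with a log2 fold change of 3.65 in place of 2.86 without sham day 14 replicate 1; Krt18 lost its call with the replicate block (0.0518), and Dmkn with the GC offset (0.0762) or the background covariate (0.0896). A larger share of mesothelial cells would raise mesothelial markers alike only where no other sorted cells express them, which was not tested. The medians therefore cannot decide on a larger share. The median was 0.44 in the mean of both days (quartiles 0.06 and 0.55), where the list was called as higher. The bound was 1.04, the fold change of Krt18 less 2 standard errors. At day 7 the list as a whole did not rise (median -0.0508, quartiles -0.46 and 0.12, against 0.89 for Gjb5). At day 14 none of these 4 genes passed the threshold (edgeR adjusted p = 0.0687 to 0.444). There the median was 0.87 (quartiles 0.64 and 1.04), below the bounds of Gjb5 (1.40) and Anxa8 (1.37) and above that of Krt18 (0.70). The upper quartile was above the bound of Dmkn (0.97). The list members did not move alike on that day, with Wt1 at a log2 fold change of 3.85. A larger share stays open for all 4 genes, as does, untested, a change within mesothelial or mesenchymal cells. Epithelial markers, a list that holds Krt18 itself, had medians of -0.40 in the mean of both days (quartiles -1.17 and -0.19, against 1.04) and -0.95 at day 7 (quartiles -1.74 and -0.11, against 0.89). The sham libraries of day 7 differed widely, however: the list averaged 4.55, 5.89 and 1.58 log2 CPM in them and 4.71, 4.59 and 3.45 after PNX. Its test pointed up there and turned without sham day 7 replicate 3. At day 14, 10 of 18 were higher, with a median of 0.12 (quartiles -0.61 and 0.67, narrowly below 0.70 for Krt18). Epithelial cells carried through the EpCAM gate are thus not excluded. Of 100 splits drawn, 6, the real one included, gave at least the 31 genes of the mean of both days, so chance is not excluded. Of the 5 others, 4 part the day 7 libraries by total counts (highest 177) and 1 parts them by surgery. Splits with day 7 parted by neither gave at most 1 gene. Parting day 7 by total counts also parts it by endothelial markers and haemoglobin, so depth cannot be told apart from cells carried through the sort. With the background covariate 77 genes passed.

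Haematopoietic markers were lower after PNX at day 14, with both sham libraries of that day above all others. A second leukocyte list of 37 genes, none shared with the first and 3 above 10 CPM in each group, had a median of -2.18 (quartiles -2.95 and -1.56), which is consistent with more leukocytes among the sorted sham cells in spite of the CD45 gate. Ctss averaged 102 CPM in sham and 21.9 CPM after PNX, and Lyz2 563 and 463 CPM. Diffuse background is argued against, since with its covariate the median of the first list was -2.19. Whether surgery or the sort made the difference stays open, with 2 sham libraries; the median was -1.37 without sham day 14 replicate 2.

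For the remaining counts, 10 lists were called at day 7 and 6 of 10 splits, the real one included, gave at least as many (highest other 16). Between days after PNX, 0 genes were called by edgeR, with 1096 at an unadjusted p under 0.05, 63 by DESeq2 and 111 by limma voom; 10 of 10 splits give at least 0 whatever the data, so their count says nothing. For the same comparison 6 lists were called, and 7 of 10 splits, the real one included, gave at least as many (highest other 10). The 10 splits of 6 libraries are too few for a share under 0.05. In the mean of both days 14 lists were called and 7 of 100 splits, the real one included, gave at least as many (highest other 15), so chance is not excluded.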

How the results depend on the processing

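In this part the X and Y covariate, the Y-expressing libraries, the background covariate, the 3 libraries of highest background left out and both GC offsets were tests chosen only after results had been seen. No named gene reversed in any alternative. Of the values for named genes 7531 stayed on their side of the threshold, 440 passed it newly, 138 lost it and 94 moved, a shift that was not itself tested. For lists the numbers were 3533, 197, 169 and 338, and 23 reversed. Counts below are genes higher at day 7, lower at day 7, higher at day 14, lower at day 14, then differing in the mean of both days, in the interaction, between days after PNX and between days after sham, which were 6, 0, 1, 0, 31, 0, 0 and 3; the cause of each change was not tested. DESeq2 gave 122, 312, 63, 45, 295, 93, 63 and 639. No filter gave 44, 134, 14, 13, 102, 8, 8 and 102, and 17 lists at day 7 in place of 10. Limma voom gave 249, 577, 0, 0, 7, 0, 111 and 0. Total counts gave 12, 0, 2, 1, 50, 1, 0 and 0. RLE size factors gave 7, 1, 1, 1, 34, 0, 0 and 4. The stricter filter gave 6, 0, 1, 0, 30, 0, 0 and 1. The fold of 1.5 gave 4, 0, 0, 0, 11, 0, 0 and 1. Only the groups compared gave 4, 1, 20 and 32, and 83 and 0 between days; for the mean and the interaction it gives no other fit. Of 15 pairs of the same replicate number, 3 correlated above 0.1, all between sham and PNX of the same day. They were replicates 2 (0.53) and 3 (0.34) of day 7 and replicate 2 of day 14 (0.18). Replicate 1 gave -0.12 at day 7 and 0.10 at day 14, and no pair across days was positive. Pairing within a day therefore stays open, and a block within the day was not fitted. With the replicate block over all groups the counts were 9, 0, 0, 0, 20, 1, 1 and 1, and 4 of the 6, 0 of the 1 and 18 of the 31 genes kept the call. With the X and Y covariate they were 15, 2, 0, 0, 34, 1, 3 and 5, and in Y-expressing libraries 6, 0, 1, 0, 2, 1, 0 and 1, where of the 6, 1 and 31 genes called 1, 0 and 1 kept the call. The background covariate gave 2, 0, 23, 12, 77, 0, 0 and 1. Leaving out the 3 libraries of highest background gave 14, 8, 8, 15, 98, 3, 0 and 16, with 18 lists at day 7 and 14 in place of 8 at day 14. The GC offset gave 2, 0, 3, 2, 50, 1, 0 and 0, and with the replicate block 5, 0, 2, 1, 21, 0, 0 and 0. Of the other genes named for the mean of both days, Anxa8, Dmkn, Krt18, Gja5, Timp1 and Tsc22d3 lost the call in the test against a fold of 1.5 (adjusted p = 0.0551 to 0.205). So did Anxa8, Krt18, Gjb5, Gja5, Adam12 and Tsc22d3 with limma voom (0.0927 to 0.235). Adam12 lost it with the GC offset and block (0.109). Without each library in turn the ranges were 3 to 39, 0 to 386, 0 to 60, 0 to 14, 8 to 192, 0 to 370, 0 to 2 and 1 to 958. The extremes came without sham day 7 replicate 1 (39, 386, 192), sham day 14 replicate 2 (60, 14, 370, 958) and PNX day 14 replicate 2 (3, 8).

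Lists called at the preset correlation numbered 10 at day 7, 8 at day 14, 14 in the mean of both days, 9 in the interaction, 6 between days after PNX and 10 after sham; with an estimated correlation they numbered 0, 0, 1, 0, 0 and 0. Without each library in turn the ranges were 10 to 19, 7 to 13, 11 to 16, 8 to 14, 5 to 8 and 6 to 17. Lists that turned direction are given with their adjusted p. Without sham day 14 replicate 2 these were alveolar fibroblast (0.950), immediate early (0.950) and cholesterol genes (0.0226) at day 14, and alveolar fibroblast (0.0262), interferon (0.246), cholesterol (0.0413) and unfolded protein genes (0.0486) between days after sham. Without sham day 14 replicate 1 they were unfolded protein genes at day 14 (0.0205) and in the interaction (0.0434), and cholesterol genes in the interaction (0.0290). Without sham day 7 replicate 3 they were epithelial markers at day 7 (1.65e-05), in the mean (0.00352) and in the interaction (0.00847). Without PNX day 14 replicate 1 it was erythroid markers at day 14 (0.00974). In Y-expressing libraries they were epithelial markers at day 7 (4.08e-05), in the interaction (5.14e-07) and after sham (0.605), and in the mean interferon (0.00230) and erythroid genes (1.81e-04). With the background covariate they were mesothelial (0.0491) and epithelial genes (0.0468) at day 7 and epithelial genes in the interaction (0.00945). Without the 3 libraries of highest background it was unfolded protein genes at day 14 (0.0191). Over the fits without 1 library, the adjusted p of these lists ranged as follows. At day 14 it ranged from 1.48e-16 to 0.950 for alveolar fibroblast, from 1.54e-06 to 0.950 for immediate early, from 2.38e-04 to 0.954 for cholesterol, from 0.0205 to 0.849 for unfolded protein and from 0.00974 to 0.669 for erythroid genes. For epithelial markers it ranged from 1.65e-05 to 0.930 at day 7, from 0.00352 to 0.895 in the mean and from 0.00847 to 0.998 in the interaction. In the interaction it ranged from 0.0185 to 0.924 for cholesterol and from 0.0434 to 0.963 for unfolded protein genes. Between days after sham it ranged from 6.86e-04 to 0.929 for alveolar fibroblast, from 6.92e-10 to 0.246 for interferon, from 1.31e-04 to 0.969 for cholesterol and from 0.00445 to 0.888 for unfolded protein genes.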

Other observations

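The test of glucocorticoid-induced genes and the choice of the other genes named in this part came after results had been seen. In the mean of both days the gap junction gene Gjb5 rose by 1.94 ± 0.28 on the log2 scale (edgeR adjusted p = 0.00638), while Gja5, the connexin 40 gene, fell by 1.69 ± 0.28 (0.0105). In the same comparison Angptl7 rose by 2.94 ± 0.40 (0.00527) and Timp1 by 1.53 ± 0.24 (0.0105). At single days Angptl7 passed at day 14 (0.0390) and not at day 7 (0.222), Timp1 at day 7 (0.00505) and not at day 14 (0.750). Gjb5 (0.0783 and 0.0687 at days 7 and 14) and Gja5 (0.0783 and 0.177) passed at neither. Angptl7 and Gjb5 kept their calls without any 1 library. Timp1 lost its call without PNX day 14 replicate 2 (0.0612), and Gja5 without sham day 14 replicate 2 (0.0737) or PNX day 14 replicate 2 (0.0714) or 3 (0.0689). Gja5 overlaps Gpr89 on the opposite strand.

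Klf15 and Tsc22d3, genes induced by glucocorticoids, fell in the mean of both days, by 1.71 ± 0.30 (adjusted p = 0.0204) and 1.57 ± 0.29 (0.0256). Tsc22d3 stood at 231 ± 52.2 CPM in sham and 170 ± 35.0 CPM in PNX at day 7, with overlapping groups. At day 14 it stood at 585 ± 410 and 90.6 ± 17.2 CPM. Without sham day 14 replicate 2 its log2 fold change in the mean of both days was -1.02. A candidate explanation is a lower response to glucocorticoids after PNX. A list of 19 other induced genes, written before their values were looked at, had a median log2 fold change of -0.38 (quartiles -0.74 and -0.16) in the mean of both days, with 15 of 19 lower. The bounds set beforehand, at most -0.5 for the explanation and above -0.2 against it, left this undecided, while the camera test of the list gave an unadjusted p of 2.52e-05 (0.00292 with an estimated correlation). At day 7 the median was -0.40 with 11 of 19 lower (camera unadjusted p = 0.113; 0.149 with an estimated correlation), and at day 14 -0.71 with 18 of 19 lower (unadjusted p = 6.88e-06; 0.00182 with an estimated correlation). The day 14 values rest on the sham libraries high in haematopoietic markers, whose part in the fall was not tested. The list was not refitted without single libraries. With the replicate block Klf15 (0.0583) and Tsc22d3 (0.150) lost their calls. Klf15 lost its call without sham day 7 replicate 3 (0.0568), PNX day 7 replicate 1 (0.0639), sham day 14 replicate 2 (0.0950) or PNX day 14 replicate 2 (0.0817) or 3 (0.0848). Tsc22d3 lost its call without PNX day 7 replicate 1 (0.0902) or 2 (0.0529), sham day 14 replicate 2 (0.108), or PNX day 14 replicate 2 (0.148) or 3 (0.157).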
